A study of Homo sapiens with 8 samples.

How the data were processed

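Polyadenylated RNA of NCI-H295R cells was sequenced as stranded single-end libraries with reads of 76 bases, per the labels' protocols. The authors deposited 1 table, with a row for each of 187 genes and, per the file headers, a column of counts for each of the 8 libraries, a log2 fold change and an FDR. The columns named for normal medium and for starvation were assigned to the control and serum-deprived samples of the same replicate number. There were 0 columns of other samples.

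The counts are estimated counts as deposited by the authors, not scaled to depth, and many are not whole numbers. Per the submitters' processing notes, cutadapt, FastQC, kallisto and edgeR were used with the build GRCh38. Versions, the transcript release and the way transcripts were summed to genes are not given in the sources used here. The table's name gives a mean count of 30, an FDR of 0.1 and a fold change of 1.5 as limits. In the file the largest FDR was 0.0993 and the smallest rise and the smallest fall among the log2 fold changes deposited by the authors were 0.59 and -0.58, while 3 genes have a mean under 30 over the 8 libraries. The deposited FDR (an adjusted p-value) and log2 fold change are printed only as the authors' values. A table of selected genes holds neither the library totals nor unchanged genes. Depth per library is therefore unknown, and methods that take most genes as unchanged have no basis in it.

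Scaling followed a rule fixed before the data were examined, as were the gene lists, the rule for named genes and the alternatives. The pseudocount and the minimum number of genes beside the empty interval, given next, were not part of that rule and were set with the table in hand. Within each group, size factors were medians over genes of the ratio to the group's geometric mean (pseudocount 0.5). Between the groups, the widest empty interval in the log2 ratios of group means with at least 20 genes on each side, left by the authors' limit on fold change, was centred on 0. It ran from -0.41 to 0.02, a shift of -0.20. Replicates 2 to 4 alone gave an interval from -0.82 to 0.34 and a shift of -0.24, and the authors' fold changes gave -0.23. Size factors were 0.846 to 1.21. On 80 simulated tables of 187 genes with known shifts the largest median error was 0.049 and the largest error 0.221 on the log2 scale. In these tables the libraries of a group were alike and every gene was changed at least 1.5-fold in all of them. In the data replicate 1 departed from the others, and the interval was 0.43 wide over 8 libraries against 1.16 over replicates 2 to 4. The simulated errors are therefore those of an easier case. Scaled counts are estimated counts divided by these factors.

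Counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3; glmQLFit and glmQLFTest) over all 8 libraries with 2 groups and no covariate, two-sided, with Benjamini-Hochberg adjustment over 187 genes and a threshold of 0.05. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. Tested on 20 simulated tables for this comparison, with 187 genes each, the step recovered 71% of genes changed 1.5-fold, 99% of genes changed 2-fold and 100% of genes changed 3-fold, and called 2.53% of unchanged genes. In these tables the size factors were known, the libraries of a group were alike and all genes had the same dispersion. Many genes were unchanged, while the deposited genes had been selected as changed. These rates need not hold for the data. Alternatives were TMM scaling, median-of-ratios size factors, no scaling, column totals, DESeq2 1.42.0, limma-voom (limma 3.58.1), a minimum mean of 100, a replicate block, the authors' thresholds and the omission of each library. Pseudocounts for normalised values, listed among the alternatives in case the table held such values, did not apply. Omissions kept the size factors of the remaining libraries. Omission of replicate 1 of both groups and a shift taken from the authors' fold changes were added after the data had been seen. Python 3.11.15 with scipy 1.17.1 was used for the remaining steps.

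Same-numbered libraries deviated together from their group means, with correlations across genes of 0.216, 0.377, 0.111 and 0.122 for replicates 1 to 4, and each library correlated best with its own number. The numbers were therefore taken to pair the libraries. The main test nevertheless had no covariate, and the pairs entered the test only as the replicate block among the alternatives. No pair of libraries within a group was a duplicate, since the chi-square per degree of freedom over genes was between 4.27 and 63.7. A gene was said to have whole counts when all 8 values lay within 0.01 of a whole number, which held for 69 genes. The other 118 include genes whose reads kallisto divided among genes or transcripts. Among these 118 are HMGCS1, MVD, FDPS, LSS, MSMO1, SCD, ABCG1, DLK1, SELENOW, SELENOH, GPX1, IL7R and ASS1. How far their reads were divided between genes is not known.

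Named genes were, among genes past the threshold whose groups did not overlap, the 10 with the largest rise and the 10 with the largest fall; all tabulated members of the lists for steroidogenesis, adrenocortical regulators, cholesterol synthesis, cholesterol uptake and LXR targets; up to 4 members of each other list; and the 5 genes of highest mean. These were 46 genes. Genes on the Y chromosome were not to be named. The 25 lists held 578 genes, of which 26 were in the table, and 12 lists had no member there. Genes outside the table were not analysed here and could not serve as a background, so no enrichment was computed. The direction of a list was compared with that of the other tabulated genes by Fisher's exact test where at least 5 members were present. Positions are those of GENCODE 29 on GRCh38, matched by gene identifier for all 187 genes. That release annotates GPX1 as a polymorphic pseudogene. Fold changes are ratios of serum-deprived to control values.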

Results

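Messenger RNA was sequenced from NCI-H295R cells, a human adrenocortical carcinoma line that makes the steroids of the adrenal cortex and is widely used as a model of it. The labels divide 8 libraries into 4 controls kept in complete growth medium and 4 libraries from cells deprived of serum and of the ITS supplement, which supplies insulin, transferrin and selenium. The design text names a single comparison, serum-deprived against control cells, and the series title places it in the context of cholesterol supply and synthesis of the adrenal androgen DHEA. The time without serum is not given in the sources used here. The deposited table held estimated counts for 187 genes that the authors had already selected. Their counts summed to between 262373 and 359195 per library, which is part of each library and not its sequencing depth. Genes outside the table were not analysed here, so the absence of a gene below says nothing about whether it changed. Because the genes were chosen on these same samples, adjusted p-values describe how large each difference was against the spread between libraries and are not independent evidence of its direction. Nothing in the labels says that libraries of a group came from separate cultures, and that spread may be technical.

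Among the tabulated genes, those of cholesterol synthesis (5 of 22 on the list) were higher after serum deprivation, while HSD3B2, 3 of 27 adrenocortical regulators and 4 of 26 selenoprotein genes were lower. In the 8 libraries, 69 genes were higher and 90 were lower in serum-deprived cells, and 28 did not pass the test (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05 over 187 genes). The genes that rose did so by a median of 0.67 on the log2 scale and those that fell had a median log2 fold change of -0.83. All 187 genes had the direction of the authors' deposited table, which lists 93 as higher and 94 as lower. In 124 genes, or 66.3%, the values of the 2 groups did not overlap. Chance gives 2.86% for unselected genes, a share that does not apply to genes selected for differing between these groups. The table holds only changed genes, so the scale between the groups had to be estimated. Without any scaling the log2 fold changes moved by a median of -0.20 and the counts were 21 higher and 91 lower. With median-of-ratios size factors they were 80 higher and 74 lower, and in DESeq2 82 higher and 77 lower, so whether more genes fell than rose depends on the scale. Without replicate 1 of both groups, all 187 genes passed, 93 higher and 94 lower. The authors' fold changes match replicates 2 to 4, as given below, so the genes appear to have been selected on these libraries. That count therefore restates the selection and is not a check of it.

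All 5 tabulated genes of the cholesterol synthesis list rose, of 22 genes on that list. They were HMGCS1, MVD, FDPS, LSS and MSMO1, which act between acetyl-CoA and cholesterol. HMGCS1, which makes HMG-CoA and lies at chromosome 5 from 43289395 to 43313512 (GRCh38), went from 25043 ± 1766 to 38799.6 ± 6779.7 scaled counts (mean ± SD, n = 4 per group), a log2 fold change of 0.63 ± 0.13 (SE). MVD, the mevalonate diphosphate decarboxylase (chromosome 16, 88651935 to 88663161), rose from 1455 ± 45.6 to 2568 ± 301, and LSS, the lanosterol synthase (chromosome 21, 46188141 to 46228824), from 5139.9 ± 209.8 to 8938 ± 1331. These were increases of 1.77-fold and 1.74-fold. FDPS and MSMO1 rose by 0.59 and 0.60 on the log2 scale. Adjusted p-values from edgeR were between 0.000517 for MVD and 0.00847 for MSMO1. All 5 also passed when adjusted over the list alone, which had to follow, since each had passed over all 187 genes. Fisher's exact test of the list's direction against the other tabulated genes, run as two-sided, gave p = 0.0288. This was the single list with at least 5 members in the table, so that no further adjustment applied. That p is the chance of 5 rises among 5 genes drawn at random from the table. It leaves out 5 falls, which are slightly more likely, as 94 of the 187 genes were lower and 93 higher. All 5 in the same direction is therefore more likely than this p states, and genes of 1 pathway are not independent. The test does not settle whether the direction of the list differed. Without scaling, 2 of the 5 passed, MVD and LSS, while HMGCS1, FDPS and MSMO1 had edgeR adjusted p-values of 0.0656, 0.05004 and 0.135.

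SCD, the stearoyl-CoA desaturase, was the 1 tabulated gene of the fatty acid synthesis list and rose 1.60-fold, from 47508 ± 6944 to 76189 ± 3809 scaled counts (edgeR adjusted p = 0.000665). ABCG1, a cholesterol exporter induced by the oxysterol receptor LXR, was the 1 tabulated gene of its list and fell 1.66-fold, from 432 ± 43.4 to 261 ± 44.4 (edgeR adjusted p = 0.0031). No gene of the list for cholesterol uptake and SREBP control was in the table.

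HSD3B2 was the only tabulated gene of the 22 on the steroidogenesis list, and it fell. It encodes the adrenal 3β-hydroxysteroid dehydrogenase, which takes pregnenolone and DHEA into the Δ4 pathway, and lies at chromosome 1 from 119414931 to 119423035. Its scaled count was 1769 ± 682 in controls and 661 ± 387 after serum deprivation, a log2 fold change of -1.42 ± 0.37 (SE; edgeR adjusted p = 0.00621). The spread was wide in both groups, with replicate 2 the highest in each (2778 in controls and 1233 after deprivation). With the numbers as a replicate block, the log2 fold change was -1.50 (edgeR adjusted p = 0.000488). The highest of the 4 serum-deprived values, 1233, lay below the lowest control value, 1294, but the groups overlapped with median-of-ratios size factors (1257 against 1209.6). The authors' deposited table gives a log2 fold change of -1.26 with an FDR of 0.0993, the largest in the table. The estimated counts of HSD3B2 were not whole numbers, and its value is uncertain as far as reads were divided with its near-identical paralog HSD3B1.

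The 3 tabulated adrenocortical regulators all fell. MRAP, the accessory protein of the ACTH receptor, went from 88.2 ± 21.8 to 41.1 ± 8.00 scaled counts (log2 fold change -1.09). INHA, the inhibin alpha subunit, went from 315 ± 19.0 to 185 ± 16.4 (log2 fold change -0.77). DLK1, a Notch-family ligand of the fetal and progenitor cortex, had the highest mean count of the table over all 8 libraries and in controls, though not after deprivation, where SCD was higher, and went from 72889 ± 4151 to 49749.8 ± 3461 (log2 fold change -0.55). Their edgeR adjusted p-values were 0.00276, 0.00101 and 0.000534. All 3 also passed when adjusted over the list alone, which had to follow from passing over all 187 genes.

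**Figure D1:**
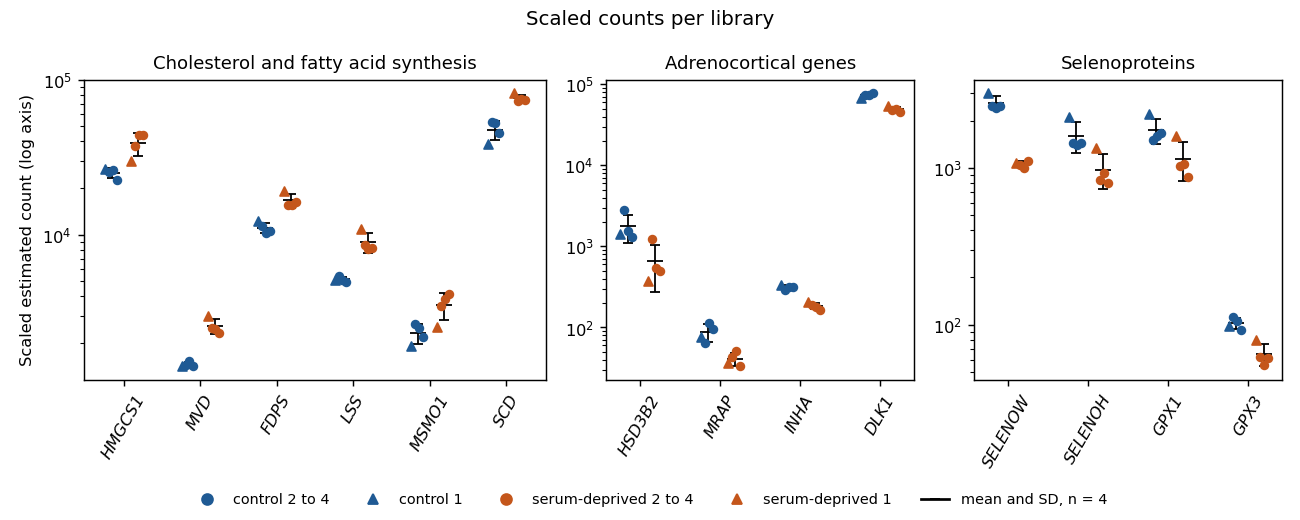
Scaled estimated counts per library (log axis) for genes of cholesterol and fatty acid synthesis, adrenocortical genes and selenoproteins, with control libraries in blue, serum-deprived libraries in orange, replicate 1 as a triangle, and mean ± SD of n = 4 in black. The 5 cholesterol synthesis genes and SCD have higher means after serum deprivation, and HSD3B2, MRAP, INHA, DLK1 and the 4 selenoprotein genes have lower ones.

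All 4 tabulated selenoprotein genes fell, of 26 symbols on that list. SELENOW, a small selenoprotein, lies at chromosome 19 from 47778572 to 47784686 and went from 2586 ± 266 to 1056 ± 48.3 scaled counts, a log2 fold change of -1.29 ± 0.12 (SE; edgeR adjusted p = 2.72e-05). SELENOH fell 1.64-fold, the plasma glutathione peroxidase GPX3 1.58-fold and the cellular glutathione peroxidase GPX1 1.53-fold, with edgeR adjusted p-values of 0.00847, 0.00571 and 0.0182. All 4 passed when adjusted over the list alone, which had to follow from passing over all 187 genes. The call for GPX1 was lost in edgeR with TMM scaling (adjusted p = 0.0545), with median-of-ratios size factors (adjusted p = 0.0823) and without serum-deprived replicate 4 (adjusted p = 0.0533), and in DESeq2 (adjusted p = 0.077).

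The 3 tabulated genes of the serum response and immediate early list fell. EGR1, a transcription factor induced by growth factors, went from 357 ± 111 to 144 ± 54.6 scaled counts (log2 fold change -1.32), ETV4, an ETS factor downstream of ERK, fell 1.81-fold and JUNB, a subunit of AP-1, fell 1.45-fold. Their edgeR adjusted p-values were 0.00334, 0.00527 and 0.0104. In the replicate 1 pair EGR1 stood at 219.9 in the control and 225 after deprivation, an order that reverses without scaling. The call for JUNB was lost with median-of-ratios size factors (edgeR adjusted p = 0.0587). ID1, a target of BMP signalling placed on the iron list, fell 2.14-fold (edgeR adjusted p = 0.00261). FN1 (fibronectin) and TNC (tenascin C) were the 2 tabulated genes of the extracellular matrix and adhesion list. They fell 1.52-fold and 1.84-fold with edgeR adjusted p-values of 0.0169 and 0.0454. Matrix genes outside that list moved both ways, as NID2 and COL4A3 rose while LAMB3, COL13A1, SPP1, SNED1 and MATN2 fell. The call for TNC was lost on leaving out control replicate 1, 3 or 4 or serum-deprived replicate 2, 3 or 4, with edgeR adjusted p between 0.0704 and 0.116, and with TMM scaling (adjusted p = 0.0799), median-of-ratios size factors (adjusted p = 0.112), DESeq2 (adjusted p = 0.109) and the shift from the authors' fold changes (adjusted p = 0.0526). FN1 had a log2 fold change of -0.91 without replicate 1 of both groups, against -0.61 with it, and its edgeR adjusted p was 0.0506 without control replicate 4 and 0.0763 with median-of-ratios size factors (DESeq2, 0.0684). Of the remaining lists, CEBPB (ATF4 list), IRF9 (interferon list) and VGF (neuronal and neuroendocrine list) fell between 1.62-fold and 1.68-fold, and ALDOC (hypoxia and glycolysis list) and ALDH1L2 (ATF4 list) rose 1.61-fold and 1.44-fold. Their edgeR adjusted p-values were between 0.000665 for ALDOC and 0.0278 for ALDH1L2. The call for ALDH1L2 was lost without control replicate 1 or 3 or serum-deprived replicate 3 or 4 (edgeR adjusted p between 0.051 and 0.0868), with column totals (adjusted p = 0.0622) and without scaling (adjusted p = 0.237). Adjusted over the list alone, the tabulated members of these lists passed as well, which had to follow from passing over all 187 genes. Members of the lists for DNA replication and S phase, mitosis, FOXO targets, ER protein folding, NRF2 and metallothioneins, lysosome and autophagy, p53 targets, RNA quality, fibroblasts, endothelium and leukocytes were not in the table.

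The 10 falls of largest size among genes without overlap were those of IL7R, CCDC3, ASS1, RARB, VCX3A, SKP1P1, HSD3B2, LAMB3, ADGRG1 and SELENOW. IL7R, the interleukin 7 receptor (chromosome 5, 35852695 to 35879603), went from 124 ± 29.3 to 21.8 ± 3.07 scaled counts and CCDC3 (chromosome 10, 12896625 to 13099652) from 284 ± 22.1 to 68.6 ± 3.55, falls of 5.69-fold and 4.14-fold. ASS1, the argininosuccinate synthase of arginine synthesis, fell 3.17-fold (log2 fold change -1.67 ± 0.18, SE), from a mean of 1552 to 489. RARB, a retinoic acid receptor, fell 3.06-fold and LAMB3, a laminin chain, 2.63-fold. VCX3A, which has close paralogs, and the pseudogene SKP1P1 fell 3.01-fold and 2.85-fold. Neither had whole counts, and their values are uncertain as far as reads were divided between similar genes. The tabulated paralog VCX3B, also without whole counts, went the other way, from 57.7 ± 33.2 to 83.4 ± 18.6 (edgeR adjusted p = 0.150). A shift of reads between VCX3A and VCX3B was not separated from a fall of VCX3A. Adjusted p-values of the 10 genes from edgeR were between 5.46e-06 and 0.00621.

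The 10 largest rises among genes without overlap were those of CELF6, OPRL1, PLEKHG5, BEST1, CDHR1, CACNA1B, PLA2G3, NFATC2, SRRM4 and CAPN3, with edgeR adjusted p-values between 0.000665 and 0.0333. CDHR1, a cadherin-related protein, rose 2.24-fold, from 109 ± 23.1 to 244 ± 23.2 scaled counts. BEST1, a chloride channel, rose 2.43-fold. CACNA1B, a neuronal calcium channel subunit, rose 1.91-fold and SRRM4, a neuronal splicing factor, rose 1.84-fold, from 128 ± 23.8 to 237 ± 16.2. CELF6, an RNA-binding protein, rose 3.23-fold from a control mean of 18.1 ± 13.1. OPRL1, the nociceptin receptor, rose 2.88-fold from a control mean of 13.5 (log2 fold change 1.53 ± 0.59, SE). Its log2 fold change was 2.44 in limma-voom and 1.00 without replicate 1 of both groups, and its scaled count in control replicate 1 was 0.0145. The call was lost with a replicate block (edgeR adjusted p = 0.0625), without scaling (adjusted p = 0.0546) and without control replicate 2 or serum-deprived replicate 1 or 2 (adjusted p between 0.052 and 0.0803). CAPN3, a calpain protease, rose 1.80-fold, a call lost without scaling (edgeR adjusted p = 0.0884). Its counts were not whole, and its value is uncertain as far as reads were divided with the overlapping tabulated gene AC012651.1.

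Among the 5 most abundant tabulated genes, DLK1, SCD, HMGCS1, MME and SERPINA5, only MME did not pass. SERPINA5, a secreted serpin, fell 1.62-fold, from 19467 ± 1418 to 12041 ± 806 scaled counts (edgeR adjusted p = 0.000403). MME, the membrane metalloendopeptidase neprilysin, had 16476 ± 5171 in controls and 21535 ± 2479 after deprivation (edgeR adjusted p = 0.0748). Its control replicate 1 stood at 24224, against 13628 to 14223 in the other controls. Without control replicate 1 the log2 fold change was 0.63 (edgeR adjusted p = 0.00108), and without serum-deprived replicate 1 it was 0.46 (adjusted p = 0.0374). It also passed with median-of-ratios size factors (edgeR adjusted p = 0.0265), in DESeq2 (adjusted p = 0.0239) and in limma-voom (adjusted p = 0.0449).

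**Figure D2:**
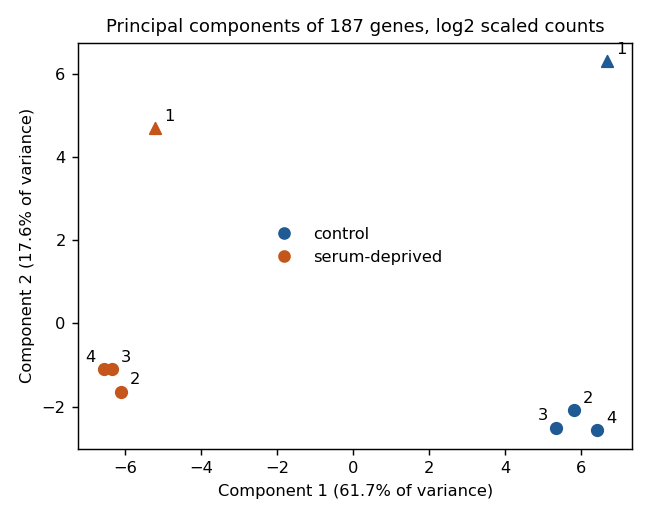
Principal components of log2 scaled counts over the 187 tabulated genes, with control libraries in blue, serum-deprived libraries in orange and replicate numbers beside the points. Component 1 (61.7% of variance) separates the groups and component 2 (17.6%) separates replicate 1 of both groups, drawn as triangles, from replicates 2 to 4. The genes had been selected for differing between the groups, so the separation along component 1 follows from that selection.

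Replicate 1 of both groups stood apart from the other libraries. Across genes, control replicates 2 to 4 had Spearman correlations of 0.977 to 0.987 with each other and of 0.9475 to 0.9499 with control 1. Serum-deprived replicates 2 to 4 had correlations of 0.969 to 0.979 with each other and of 0.919 to 0.927 with serum-deprived 1. Both replicate 1 libraries were nearer to their own group than to the other, where their correlations with replicates 2 to 4 were at most 0.8645. The log2 fold changes of the authors' deposited table matched the ratios of mean counts of replicates 2 to 4 with an SD of 0.0143 around a constant offset of -0.23, against an SD of 0.188 with all 8 libraries. No other omission of up to 1 library per group, of 25 choices tried, gave an SD under 0.152.

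**Figure D3:**
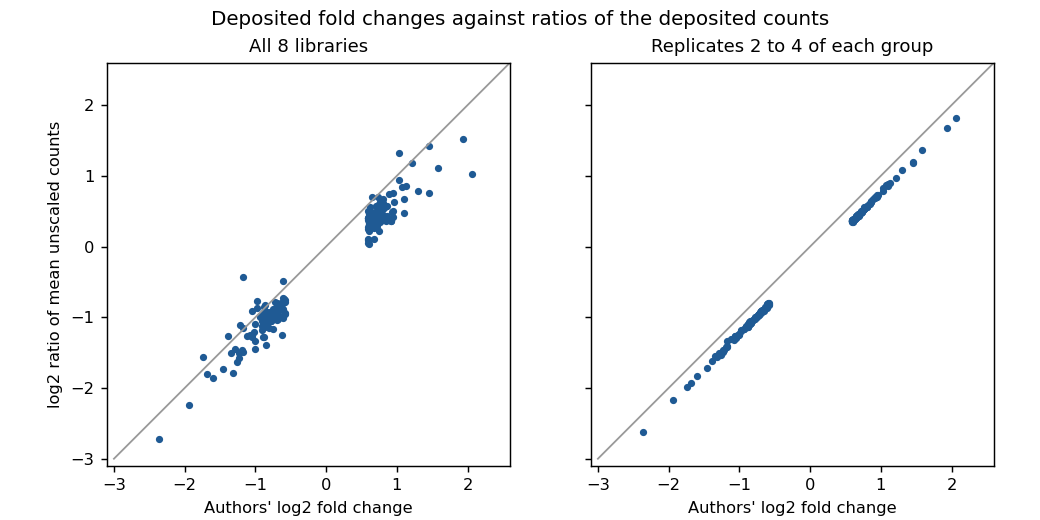
The authors' log2 fold change (x axis) against the log2 ratio of mean unscaled counts, serum-deprived over control (y axis), for 187 genes, with all 8 libraries on the left and replicates 2 to 4 on the right. The grey line marks equality. The points on the right follow a line at a constant offset of -0.23, with an SD of 0.0143 against 0.188 on the left.

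The replicate 1 pair therefore gives a reading of direction that the authors' fold changes do not draw on. In that pair, 154 of the 187 genes (82.4%, exact 95% interval 76.1 to 87.5%, counting error over genes only, which are not independent) moved the way the authors' deposited table gives. The count was 71 of 93 for genes listed as higher and 83 of 94 for genes listed as lower. The median log2 ratio in the pair was 0.49 for the former and -0.73 for the latter, against medians of 0.71 and -0.84 in the authors' deposited table. With 1 library per group, the pair has no replicate check. The 5 cholesterol synthesis genes were higher in the pair, by 0.18 for HMGCS1 to 1.10 for LSS on the log2 scale. The direction of HMGCS1 rested on the scaling. Without the size factors (0.996 for control 1 and 0.848 for serum-deprived 1) its count was slightly lower after deprivation. HSD3B2 was lower, at -1.92, and the 4 selenoprotein genes were lower, from -0.30 for GPX3 to -1.47 for SELENOW. Among genes that moved the other way were FN1 at 0.26 and MME at -0.43.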

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

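The tests of a label swap and of a shared batch were chosen after the result was seen. Among 92 groups of 4 libraries (46 named genes in each group), 9 held a library far from the other 3 by Dixon's test, where chance alone gives about 4.6. All 9 were replicate 1. In control replicate 1, scaled counts were 111.5 for BEST1, 2982 for SELENOW (others 2403 to 2486), 2119.9 for SELENOH (others 1401 to 1441) and 24224 for MME (others 13628 to 14223). In serum-deprived replicate 1 they were 643 for CACNA1B (others 333 to 365), 79.0 for PLA2G3 (others 63.9 to 66.2), 19268 for FDPS (others 15559 to 16146), 10914 for LSS (others 8090.2 to 8538) and 225 for EGR1 (others 109.7 to 126).

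A swap of labels within the pair is argued against: on an axis from control replicates 2 to 4 at 0 to serum-deprived replicates 2 to 4 at 1, control 1 lay at 0.0795 (bootstrap 95% interval over genes -0.0668 to 0.220) and serum-deprived 1 at 0.833 (0.710 to 0.950). Reads shared between similar genes stay open as a partial source: 10.1% of the 69 genes with whole counts moved against the authors' direction in the pair (exact 95% interval 4.18 to 19.8%), against 22.0% of the 118 others (two-sided Fisher's exact test, p = 0.047). A batch or culture day shared by the pair remains a candidate explanation, since the deviations of the 2 libraries from replicates 2 to 4 correlated across genes (r = 0.216, bootstrap 95% interval 0.0258 to 0.424, Spearman's rho = 0.227). The deviations of the replicate 2 pair correlated more strongly (r = 0.377), but they were taken from group means that include replicate 1. A departure shared by the replicate 1 pair enters the deviations of replicates 2, 3 and 4 alike. It does not by itself give replicate 2 a higher value than replicates 3 (r = 0.111) and 4 (r = 0.122). Each library also correlated best with its own number, so r = 0.216 does not single out the replicate 1 pair. The labels name no batch, and a difference in the state of the cells was not tested.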

How the results depend on the processing

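The omission of replicate 1 of both groups, the shift taken from the authors' fold changes and the alternatives for the direction in the replicate 1 pair and for overlap between groups were chosen after seeing the data. The count of changed genes was 159 with all 8 libraries and ran from 133 (without control replicate 3 or serum-deprived replicate 4) to 173 (without serum-deprived replicate 1) when single libraries were left out (53 to 82 higher, 78 to 91 lower). It was 91 of the 107 genes tested with a mean of at least 100 (36 higher, 55 lower), where fewer genes were tested, 112 without scaling (21 higher, 91 lower), 154 with median-of-ratios size factors (80 higher, 74 lower), which moved the log2 fold changes by a median of 0.15, 143 at the authors' limits of adjusted p and fold change (57 higher, 86 lower), 151 with TMM and 159 with DESeq2 (82 higher, 77 lower), which gave no adjusted p for 1 gene. Without scaling, 2 cholesterol synthesis genes passed; under each of the other alternatives run, 5 did. Selenoprotein calls were 3 or 4 of 4, and 3 of the 3 tested with a mean of at least 100, where GPX3 was not tested. With the numbers as a replicate block, 162 genes passed, 154 of them also without it, and of the 46 named genes only OPRL1 changed its call (log2 fold change 1.61). Of the 46 named genes, 35 kept their side of the threshold under all alternatives that tested them and none reversed. The replicate 1 pair kept the authors' direction in 149 (no scaling) to 155 genes (authors' shift). Groups did not overlap in 97 (no scaling) to 124 genes, and of the 20 genes named for the largest changes without overlap, HSD3B2 and ADGRG1 overlapped with median-of-ratios size factors, ADGRG1 with the authors' shift, and 8, ADGRG1 among them, without scaling. Other splits of the 8 libraries were also fitted: the real split was 1 of 35 with as many calls (159, the highest other 1; among the 8 splits that part all 4 pairs the highest other was also 1), but the genes had been chosen by the authors for this grouping, so chance can be neither excluded nor shown by this count. Library depth is unknown, and genes with few counts, such as OPRL1 and CELF6, are the least precise.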

Other observations

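The readings of replicate 1 and the shuffling of directions over genes were chosen after the values were seen. The genes of this paragraph were picked because their values had been seen to fall, belong to no list fixed beforehand and were not tested as a group. RARB, a retinoic acid receptor, fell 3.06-fold. STRA6, the cellular importer of retinol, went from 84.5 ± 3.25 to 41.9 ± 6.98 scaled counts (mean ± SD, n = 4), RBP5, a retinol-binding protein, fell 2.38-fold, THRB, a thyroid hormone receptor, fell 1.98-fold and KLF9, a factor induced by thyroid hormone and glucocorticoids, fell 2.38-fold. The edgeR adjusted p-values of the 5 genes were between 0.000372 and 0.00104.

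The genes of this paragraph were also picked after their values were seen and form no tested group. NAB2, a co-repressor of EGR1, fell 1.53-fold (edgeR adjusted p = 0.0211), and ID3, a BMP target, fell 1.70-fold (adjusted p = 0.00609). IGFBP7 fell from 1608 ± 176 to 785 ± 148 scaled counts, while IGFBP2 rose from 1787 ± 504 to 2810.1 ± 959 (edgeR adjusted p = 0.0311). TP53INP2, an autophagy regulator, fell 1.91-fold (edgeR adjusted p = 0.00387) but stood at 0.11 in the replicate 1 pair on the log2 scale. The sign of that value reverses without scaling.

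The fall of the 4 selenoprotein genes may, as a hypothesis, follow from selenium withdrawn with the ITS supplement. In the replicate 1 pair 4 of 4 were lower, but so were 83 of the 94 genes that the authors' deposited table lists as lower, and any cause of the fall predicts this. Serum, insulin and transferrin were removed at the same time, so these cannot be told apart. Short transcripts in the table were mostly lower: of 62 other genes with transcripts of at most 2503 nucleotides, 43 were lower, and the mean log2 fold change of the selenoprotein genes (-0.82) was at percentile 14.45 of 10000 random sets of 4 such genes. This test does not separate the selenoprotein genes from other short genes of the table.

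Genes that the authors' deposited table lists as lower were shorter than those listed as higher, with median longest transcripts of 2539 and 4235 nucleotides. Shuffling directions over the genes gave as large a difference with p = 3.0e-05 (permutation test, 100000 draws, two-sided), which argues against chance, although genes are not independent. A length bias of the libraries could give such a pattern, and it would predict a trend also within each direction. Spearman's rho of fold change with transcript length was -0.0336 within the higher genes (bootstrap 95% interval -0.240 to 0.176) and -0.0678 within the lower ones (-0.264 to 0.142), intervals too wide to settle it. With the genomic span, introns included, rho was -0.240 within the higher genes (-0.418 to -0.0497), against such a trend, but spans are not the length of the sequenced transcripts, and no biological explanation was tested.

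As a hypothesis, the rise of the cholesterol synthesis genes may reflect sterol-responsive transcription after serum withdrawal. In the replicate 1 pair 5 of 5 cholesterol synthesis genes were higher, HMGCS1 only with scaling. But so were 71 of the 93 genes that the authors' deposited table lists as higher, and any cause of the rise predicts this. Loss of insulin, which also acts on this pathway, was not separated from loss of serum in this design, and the cause of the rise stays open.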
